A study of Homo sapiens with 2 samples.

How the data were processed

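Total RNA from 2 samples of WPMY1 cells, 1 with a control shRNA and 1 with a WNT5A shRNA, had been labelled with Cy3 and hybridised to 1 Agilent one-colour array each, per the labels' protocols. The spot intensities were extracted with Agilent Feature Extraction 12.0.3.1, per the file headers, which subtracts the background and a spatial trend within each array and gives a processed intensity and its error per spot. The authors also deposited a table of intensities for the same spots. Set against the scanner values, it was the processed intensity times 1 constant per array (5.06 and 5.05), on a linear scale and not centred by gene, with column medians of 51.9 and 49.1; how the constants were chosen is not given in the sources used here.

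Each array held 62976 spots, of which 60901 were not controls, for 58201 probes. The 75th percentile of the processed intensity was 200 and 202 for the control shRNA and WNT5A shRNA arrays, 31079 and 29795 spots were well above background, and no spot was saturated (0 on each array). Flagged outliers (119 spots on each array) were left out. Replicate spots of 1 probe had a median SD of 0.0543 and 0.0547 on the log2 scale. The 8 spike-in controls with enough spots differed between the arrays by -0.09 to -0.04. The number of arrays limits the precision, since 1 array per group leaves the spread between cultures unknown.

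The main value was log2 of the processed intensity minus the 75th percentile of the array over its non-control spots, replicate spots were averaged, and the difference was WNT5A shRNA minus control shRNA. Probes were named through their RefSeq accessions, without versions, in the RefSeq gene table of GRCh38.p14; since the arrays' grid was built on GRCh37, no coordinates are given and only names and gene order were used. Of 58197 probes left after outlier flags, 31101 were named by 1 gene, 0 by several, and 27096 stayed unnamed. The probe with the highest mean signal stood for a gene, taken among its probes well above background on both arrays where there were any, since a gene counts as dim only where all its probes are. Of 22437 genes, 14534 were well above background on both arrays, 765 only on the control shRNA array, 262 only on the WNT5A shRNA array, and 6876 on neither. A gene seen on 1 array has a bound, "at least N-fold", set against the higher of the dim probe's own signal and the lowest signal among probes well above background on that array. The bound takes no account of the scanner error. Where the dim probe's own signal was the higher, the bound is the measured difference. Of the genes past 2-fold, 127 had several measured probes, and in 10 of them the probes differed in sign.

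No test was made. Lists of genes were described by the percentile of their median among 10000 random lists matched on mean signal in 20 bins; a list needed 3 measured members. The 35 lists were fixed before the data were examined, and 9 of their members, in 6 lists, had no named probe. The genes named are WNT5A; the 15 highest and 15 lowest differences among symbols (no clone, locus or long non-coding placeholder names) measured on both arrays with at least median signal, 6802 genes; the 5 highest bounds in each direction; and, for each list, up to 2 highest and 2 lowest members and any member at least 2-fold different. Some genes that this rule takes are not reported here. ROR2, AXIN2 and CCN1 in the report, and the genes of the lists and clusters in the closing section, were chosen after their values were seen. The further lists of the closing section (complement, MHC class I, NF-kB targets, other RNA sensing genes and 2 histone lists) were likewise written after the data were seen. For the order along chromosomes, a local median was taken over 61 measured genes and set against 200 shuffled orders.

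The alternatives were normexp background correction (limma 3.58.1, offset 50), quantile normalization, scaling to the median of detected probes, removal of a loess trend (span 0.3), all probes without a background filter, the mean of a gene's probes, the deposited table, thresholds of 1.5-fold and 3-fold, counts without bounds, and random lists not matched on signal. Normexp used the median spot intensity, since the scanner files used here hold no mean spot intensity. Scaling to the 75th percentile of detected probes and removal of the local chromosomal median were added after the data were seen. Calling was tested on simulated differences for the 14534 genes, with the noise of replicate spots only. List scoring was tested on the observed differences, with a shift added to randomly drawn lists. Of genes given a log2 difference of 1.5 or 2, 100% were called at 2-fold, of those given 1, 44%, and of those given 0.5 or none, 0%. This noise (SD 0.0771 for a difference) was smaller than the median scanner error of 0.204 and held no spread between cultures. These shares are therefore not error rates for the genes counted here. Lists of 20 genes fell outside the limits in 8% of draws with no shift, 92% with a shift of 0.3 and 100% with 0.5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.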

Results

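Gene expression was measured in WPMY1, an established line of human prostate stromal cells with a myofibroblast phenotype. One sample had been transduced with lentivirus carrying a control shRNA against luciferase, a reporter gene that human cells lack, and 1 sample with an shRNA against WNT5A, a secreted WNT ligand that acts mainly outside the beta-catenin route. Each RNA was labelled with Cy3 and hybridised to 1 array. The stated question was how depletion of WNT5A alters gene expression in stromal myofibroblasts. With 1 array per group there was no replicate check, so no test was made and no p-value is given. Sizes of differences are reported, and their errors come from the scanner software and cover the measurement on the array only. Both arrays lay on the same slide and were scanned in the same scan. The arrays had like brightness, with a 75th percentile of 200 for the control shRNA array and 202 for the WNT5A shRNA array, and 51.0% and 48.9% of the spots were well above background. All differences below are log2 values, WNT5A shRNA minus control shRNA, after scaling each array to its own 75th percentile.

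WNT5A itself was read by 1 probe (NM_003392) at a signal of 1990 in the control shRNA array and 718 in the WNT5A shRNA array. The difference was -1.49 with a scanner error of 0.204 (95% interval of the scanner error -1.88 to -1.09), so that WNT5A was 2.80-fold lower and stood at 35.7% of its control level. The software gave this same error to many other bright genes, so the interval is not a spread observed for WNT5A. The direction matched the label of the sample. WNT5A remained at least 2-fold lower under every processing alternative listed with the methods.

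Of 22437 genes with a named probe, 14534 were well above background on both arrays. Their differences had a median of 0.02 and an SD across genes of 0.503, and the SD was larger in the dimmest 25% of genes (0.647) than in the brightest 25% (0.334). At least 2-fold higher signal in the WNT5A shRNA array was seen for 347 genes, and at least 2-fold lower signal for 667 genes, so that 34.2% of the genes past 2-fold were higher. Under the normexp background correction these counts were 75 and 244, of which 23.5% were higher. Of the 347 higher genes 107, and of the 667 lower genes 173, were well above background on 1 array only and are known by a bound.

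Among genes with above-median signal, the lowest differences were those of CCDC3 (-3.90, 14.95-fold lower), a secreted coiled-coil protein, and OCIAD2 (-3.82, 14.1-fold lower). They were followed by the matrix glycoprotein gene EMILIN2 (-2.71), the monooxygenase gene CYP1B1 (-2.70, with its second probe at -2.56), QPRT of NAD synthesis (-2.52), the small heat shock protein gene HSPB1 (-2.34, with 3 probes between -2.45 and -2.34) and the neurofilament gene NEFL (-2.26). The procollagen processing enhancer PCOLCE (-2.13), G0S2 (-2.08), the chemokine gene CXCL12 (-2.02), the adaptor gene NCK2 (-2.02), the imprinted long non-coding RNA MEG3 (-1.97), PHLDA1 (-1.85), ARHGDIB (-1.82) and ANXA6 (-1.81) completed the 15 lowest. The 15 highest were led by TULP3 (2.28, 4.86-fold higher), which acts in ciliary trafficking. Of the others, 10 were histone genes, namely H1-2 (2.10), H2BC12 (2.04), H2AC19 (1.95), H2BC14 (1.73), H2BC8 (1.68), H2BC4 (1.68), H2BC10 (1.66), H2BC9 (1.66), H2BC17 (1.59) and H2BC5 (1.59). Copies of these histone genes are similar in sequence, and measured genes beside the main histone cluster had a median difference of 0.30. The remaining genes were CCDC90B (1.63), the tissue factor gene F3 (1.62), the phospholipid flippase gene ATP8B1 (1.61, where the local median along chromosome 18 was 0.43) and SLC6A10P (1.54, with a second probe at -0.03).

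Some genes were well above background on 1 array only. RIPOR3 was at least 57.1-fold lower in the WNT5A shRNA array, and the transcription factor gene RUNX3 at least 32.1-fold lower. RIPK4, PRXL2A and ASB9 were at least 11.5-fold, 10.1-fold and 9.80-fold lower. In the other direction, PDX1, SEMA5B, CD53, ACTL7B and LZTS1 were at least 14.6-fold, 14.2-fold, 12.5-fold, 12.2-fold and 11.7-fold higher. These 5 genes had signals of 91.7 to 114 in the WNT5A shRNA array, below its 75th percentile of 202.

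**Figure D1:**
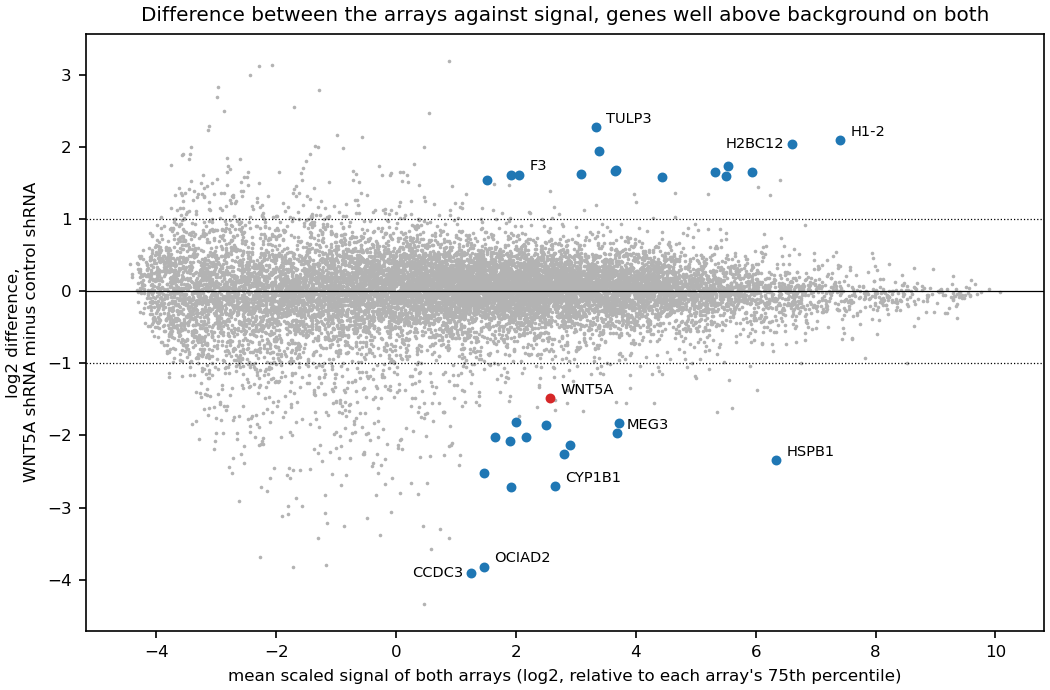
Log2 difference of each gene well above background on both arrays (y axis, WNT5A shRNA minus control shRNA) against its mean scaled log2 signal (x axis, relative to the 75th percentile of each array); 1 array per group. Blue points are the 15 highest and 15 lowest genes with above-median signal, the red point is WNT5A at -1.49, and dotted lines mark 2-fold. The spread is wider on the dim side, and H1-2 at 2.10 and HSPB1 at -2.34 stand out among bright genes.

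Gene lists fixed before the data were examined were described by the median difference of their measured members and its percentile among 10000 random lists of the same size and signal. Of 34 lists with a median, 10 lay below the 2nd percentile and 3 above the 98th, where 1.36 would be expected outside these limits by chance if genes were independent. Among the members named below and measured on both arrays, NOX4, ANGPT1, FGF5, IFI44L, BST2, LUM, ELN, MMP11, NFATC4, SC5D and FLT1 had signals of at most 54.1 on each array. Dim genes measured on both arrays had the wider spread given above. The list members known by a bound were dim too, with signals of at most 58.8 (POSTN, control shRNA) on their brighter array.

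**Figure D2:**
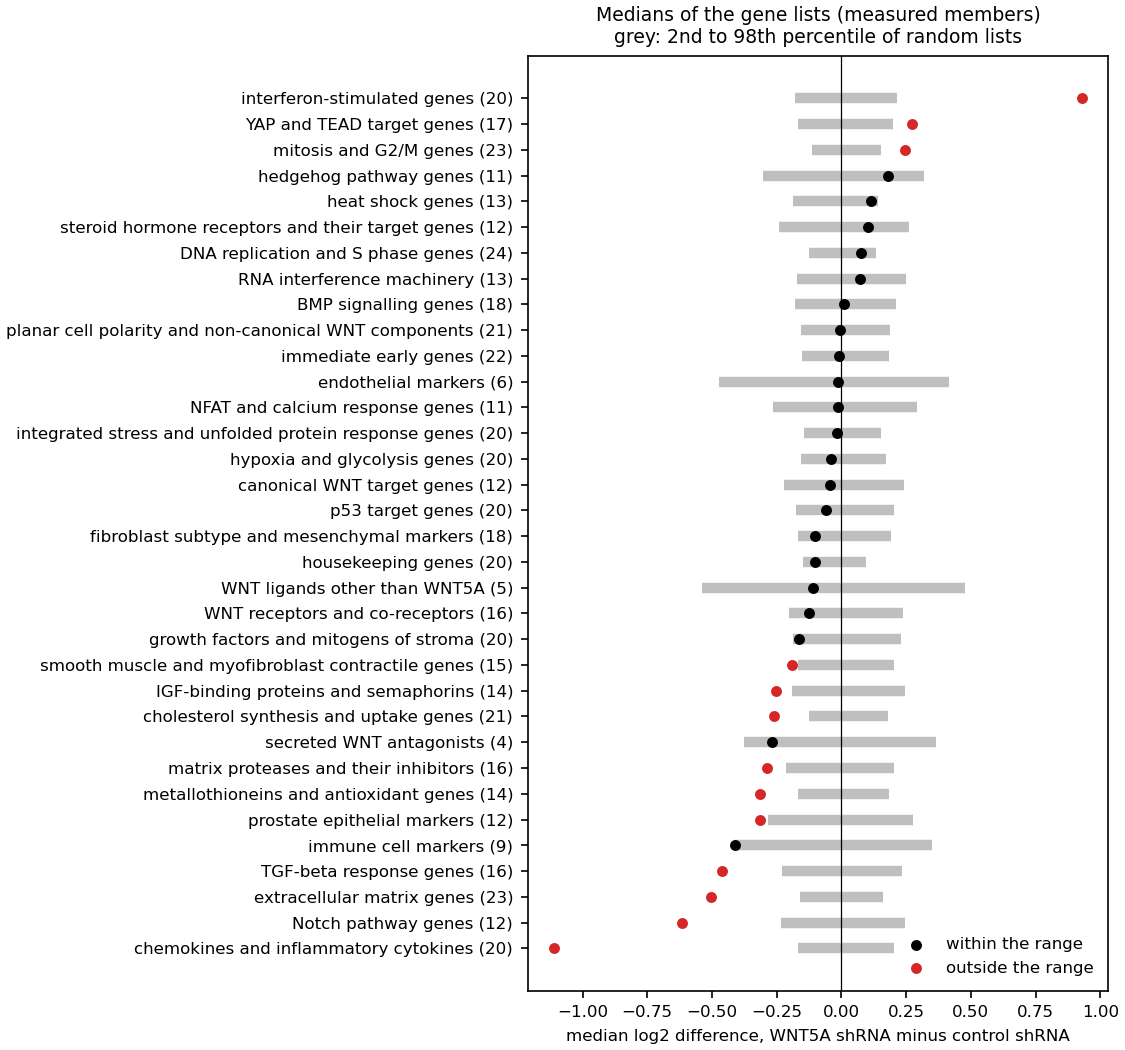
Median log2 difference (x axis, WNT5A shRNA minus control shRNA) of each of 34 gene lists, with the number of measured members in brackets; 1 array per group. Grey bars span the 2nd to 98th percentile of 10000 random lists, and red points lie outside them. Chemokines and inflammatory cytokines (-1.11) and interferon-stimulated genes (0.93) stand at the 2 ends.

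The WNT pathway lists lay within the limits. The other WNT ligands had 5 measured members with a median of -0.11 (percentile 28.9), although WNT5B, the closest relative of WNT5A, was higher (1.06, 2.09-fold) and WNT10B was at least 2.89-fold lower; the mean of the list was 0.05. WNT receptors and co-receptors had a median of -0.13 over 16 members (percentile 7.10). Among them the WNT5A receptor genes ROR2 and ROR1 stood at -0.57 and 0.77, FZD8 at -0.74 and FZD6 at 0.59, and MCAM was 2.54-fold lower (-1.35, in a stretch of chromosome 11 with a local median of -0.44). Secreted WNT antagonists had 4 measured members with a median of -0.27 (percentile 5.53, and 0.87 with all probes), of which FRZB was 3.87-fold lower (-1.95). Canonical WNT targets had a median of -0.04 over 12 members (percentile 26.0), 6 of them above and 6 below 0; the median was above 0 with all probes (0.015) or with a gene's probes averaged (0.039). AXIN2, a common readout of beta-catenin activity, stood at 0.20, CCND1 at 0.99 and MYC at -0.46, and TNFRSF11B was 3.12-fold lower (-1.64). Planar cell polarity and non-canonical components (-0.01, 21 members, percentile 39.0, above 0 with quantile normalization or averaged probes) included PRICKLE2, just past 2-fold lower. In the NFAT and calcium response list (-0.01, 11 members, percentile 33.6, above 0 with all probes or under normexp) NFATC4 was lower (-1.42) and NFATC2 at least 2.79-fold lower.

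Extracellular matrix genes were lower as a group, with 18 of 23 measured members below 0 and a median of -0.50, below each of the 10000 random lists. The fibrillar collagen genes COL3A1 (-1.53), COL1A2 (-1.50) and COL1A1 (just past 2-fold), the collagen VI gene COL6A3 (-1.15), the matricellular gene THBS2 (-1.68) and the small proteoglycan genes LUM (-1.63) and DCN (-1.24) were at least 2-fold lower. POSTN was at least 6.38-fold lower. BGN was 3.41-fold lower as measured, with a scanner error of 0.399, and was dim in the WNT5A shRNA array. LUM and DCN lie side by side on chromosome 12, where the local medians were -0.35 and -0.30. The basement membrane collagen gene COL4A1 (0.37) and elastin, ELN (0.34), lay on the other side of 0, and the local median at COL4A1 was 0.42. TGF-beta response genes had a median of -0.46 over 16 members (percentile 0.03): SNAI2 (-1.53), SNAI1 (-1.22) and BHLHE40 (-1.53) were lower, the oxidase gene NOX4 was higher (1.85) and CCN2 stood at 0.47. Matrix proteases and their inhibitors had a median of -0.29 over 16 members (percentile 0.40). TIMP4 (-2.87), ADAMTS4 (-1.48), PLAU (-1.37), MMP11 (-1.35) and the gelatinase gene MMP2 (-1.19) were lower, and the stromelysin gene MMP3 was higher (2.17, 4.49-fold, with a local median of 0.32 on chromosome 11). This list lay within the limits when all probes were used (-0.093) or a gene's probes were averaged (-0.18). Contractile genes of smooth muscle and myofibroblasts lay at the edge, with a median of -0.19 over 15 members (percentile 1.19, and 2.73 without matching on signal). ACTA2, the usual myofibroblast marker, stood at -0.56, TNS1 at -1.36 and the enteric actin gene ACTG2 at 1.15.

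The list median farthest from 0 was that of chemokines and inflammatory cytokines, with 17 of 20 measured members below 0 and a median of -1.11, below each of the random lists. IL1B was 11.96-fold lower (-3.58), CCL7 9.25-fold lower (-3.21) and IL6 6.32-fold lower (-2.66). CXCL12 (-2.02), CXCL6 (-1.84), CSF2 (-1.76), CCL2 (-1.67), CXCL1 (-1.62), CXCL5 (-1.32), IL11 (-1.17) and CXCL8 (-1.05) were also at least 2-fold lower, and TNFAIP6 at least 2.68-fold lower. Against this direction, the T cell chemokine gene CCL5 was 5.86-fold higher (2.55) and the alarmin gene IL33 at least 6.05-fold higher, while TNFAIP3 stood at 0.46. The median was -0.50 when dim probes were included. It was then no longer the farthest from 0, with interferon-stimulated genes at 0.93 and extracellular matrix genes at -0.53.

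Interferon-stimulated genes were higher as a group, with 18 of 20 measured members above 0 and a median of 0.93, above each of the random lists. IFI44 was 5.57-fold higher (2.48), OASL 3.99-fold and the RNA sensor gene IFIH1 3.13-fold (1.65). IFI44L (1.48), BST2 (1.23), IFI6 (1.09), the sensor gene RIGI (1.08) and IFIT3 (1.02) were past 2-fold, and RSAD2 was at least 5.37-fold higher. BST2 lies in a stretch of chromosome 19 with a local median of 0.35. IFITM1 (-0.91, local median -0.32 on chromosome 11) and MX2 (-0.22) lay below 0. The 10 brighter members had a median of 0.54 and the dimmer ones 1.02, and under normexp the median of the list was 0.51.

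Notch pathway genes had 10 of 12 measured members below 0 and a median of -0.62, below each of the random lists. The median was -0.47 under normexp, -0.39 with all probes and -0.74 with local medians removed. The receptor gene NOTCH3 was 9.82-fold lower (-3.30), although the local median on chromosome 19 was 0.33. The ligand gene JAG1 (-1.55) and the target genes HEY1 (-1.33) and HES1 (-1.25) were lower, HEYL was at least 2.12-fold lower, and NOTCH1 stood at 0.03. YAP and TEAD target genes were higher, with a median of 0.27 over 17 members (percentile 99.7), led by ANKRD1 (2.14, 4.40-fold) and F3 (1.62), whereas NT5E stood at -0.48 and the much used target CCN1 at 0.01. BMP signalling genes were centred near 0 (0.01, 18 members, percentile 45.2, below 0 after loess or scaling to detected probes' 75th percentile, with a mean of -0.06), with GREM1 (-1.52) and CHRD (-1.47, with a second probe at 0.23) lower and BMP7 at least 2.21-fold higher. Hedgehog pathway genes had a median of 0.18 over 11 members (percentile 87.0) and a mean of -0.15, with GAS1 at -1.31, GLI1 at -0.97 and PTCH1 at 0.54. Under normexp the median of this list was 0.032.

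Mitosis and G2/M genes were slightly higher, with 18 of 23 members above 0 and a median of 0.25 (percentile 99.97), from CCNB1 at -0.31 to MKI67 at 0.51, and none past 2-fold. DNA replication and S phase genes had a median of 0.07 over 24 members (percentile 87.0), from RRM1 at -0.42 to CCNE1 at 0.59. The lists of p53 targets (-0.06, percentile 16.7), integrated stress and unfolded protein response genes (-0.02, percentile 35.6, above 0 with quantile normalization or normexp) and heat shock genes (0.12, percentile 96.4, with a mean of -0.04) lay within the limits. In these lists ASNS was 2.56-fold higher (1.36), HSPA1B stood at 1.01, and HSPB1 was 5.06-fold lower (-2.34).

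Of the metabolic and secreted groups, cholesterol synthesis and uptake genes had 17 of 21 members below 0 and a median of -0.26 (percentile 0.05). SC5D was 2.46-fold lower (-1.30), INSIG1 stood at -0.77, and the local medians at SC5D and INSIG1 were -0.43 and -0.38. With local medians removed, the median of the list was -0.17. Metallothioneins and antioxidant genes had a median of -0.31 over 14 members (percentile 0.04), with MT1F (-1.75) and MT1M (-1.06) lower and HMOX1 at 0.92. IGF-binding proteins and semaphorins had a median of -0.25 over 14 members (percentile 0.64), which was -0.028 (percentile 30.6) with local chromosomal medians removed; PLXND1 (-1.57), IGFBP7 (-1.14) and IGFBP2 (-1.11) were lower, IGFBP1 was at least 2.03-fold lower, and SEMA3B was higher (1.17). Stromal growth factors had a median of -0.16 over 20 members (percentile 3.06, and 1.42 under normexp). HGF, a mitogen for epithelium, was 8.48-fold lower (-3.08) and IGF2 at least 4.93-fold lower, whereas ANGPT1 (1.42) and FGF5 (1.35) were higher. ANGPT1 and FGF5 were dim, at signals of 11.1 and 13.3 in the control shRNA array and 30 and 34.2 in the WNT5A shRNA array. Hypoxia and glycolysis genes (-0.04, 20 members, percentile 26.0, 1.76 with all probes, with a mean of 0.02) included ANGPTL4, 6.93-fold higher (2.79, local median 0.41 on chromosome 19), and ALDOC, lower (-1.26). Immediate early genes (-0.01, 22 members, percentile 34.04, 1.40 with local medians removed, above 0 with all probes or under normexp) ranged from JUN at -0.75 to SPRY2 at 0.84. Steroid receptors and their targets (0.10, 12 members, percentile 74.3, with a mean of -0.03, below 0 with all probes or with local medians removed) included TSC22D3, lower (-1.32), and PGR (1.17) and NR3C2 (1.04), both higher. RNA interference machinery had a median of 0.07 over 13 members (percentile 59.4).

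Fibroblast subtype and mesenchymal markers had a median of -0.10 over 18 members (percentile 8.82, and 1.69 with local medians removed), and FAP (-2.58) and FBLN2 (-2.19) were lower. Prostate epithelial markers had 12 measured members with a median of -0.31 (percentile 1.33, 4.45 under normexp, and 0.026 as the median with all probes), with KRT18 at -0.92. Immune cell markers had 9 members with a median of -0.41 (percentile 2.11, at the edge of the limits, and below the 2nd percentile in 7 of the 10 list alternatives, at 0.46 to 1.92), all below 0, with CSF1R 4.35-fold lower (-2.12) and KIT at -1.67. Under normexp the median of the immune list was -0.22. Endothelial markers were centred near 0 (-0.01, 6 members, percentile 48.1, above 0 with quantile normalization, normexp, all probes or local medians removed), and FLT1 (-1.79) and PECAM1 (at least 3.20-fold) were lower. Only 2 neural and neuroendocrine markers were measured, ENO2 (0.21) and TUBB3 (0.24), and S100B was at least 5.57-fold lower. Housekeeping genes had a median of -0.10 over 20 members (percentile 8.97), with B2M at 0.04.

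**Figure D3:**
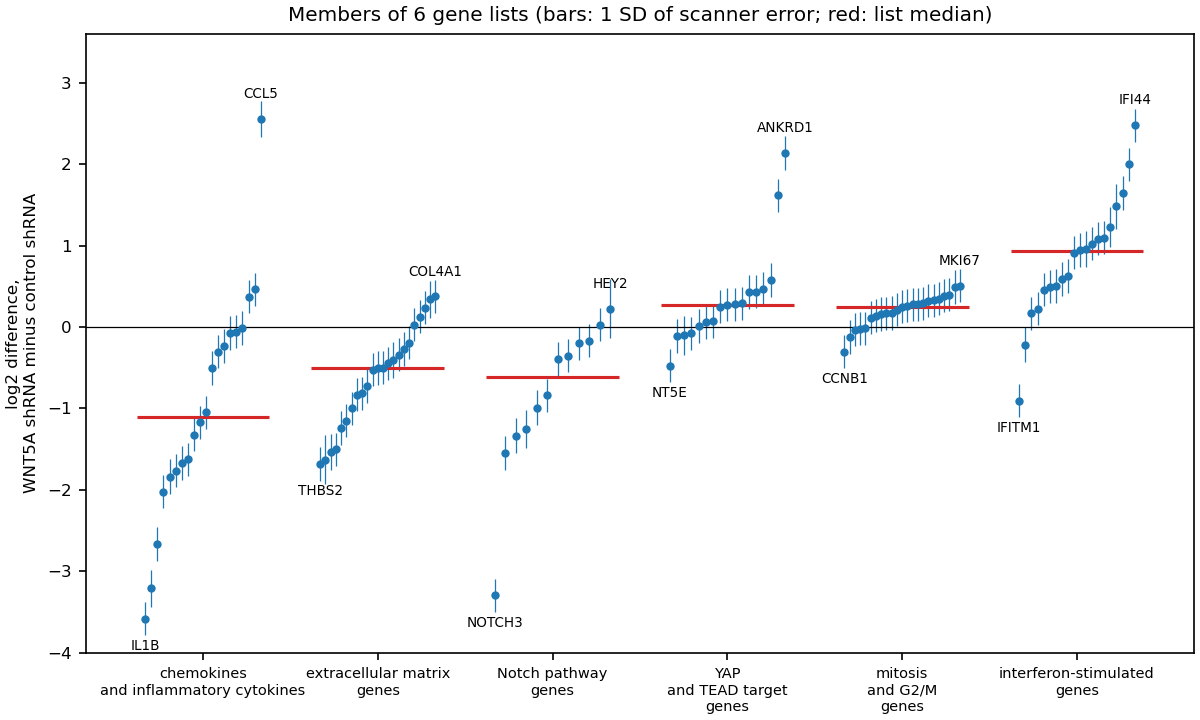
Log2 difference (y axis, WNT5A shRNA minus control shRNA) of each measured member of 6 gene lists, ordered within each list; 1 array per group. Points are genes, bars are 1 SD of the scanner error, red lines are list medians, and the lowest and highest member are named. Chemokines run from IL1B at -3.58 to CCL5 at 2.55, and interferon-stimulated genes from IFITM1 at -0.91 to IFI44 at 2.48.

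Differences were also shared between neighbouring genes. In chromosomal order, the median difference in windows of 61 measured genes had an SD of 0.155, against at most 0.0569 in 200 shuffled gene orders. Over whole chromosomes, genes of chromosomes 18 (median 0.35), 6 (0.26), 19 (0.24) and 9 (0.16) were higher and those of chromosomes 7 (-0.17), 12 (-0.14) and 5 (-0.13) lower in the WNT5A shRNA array. The local median at WNT5A was 0.06.

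**Figure D4:**
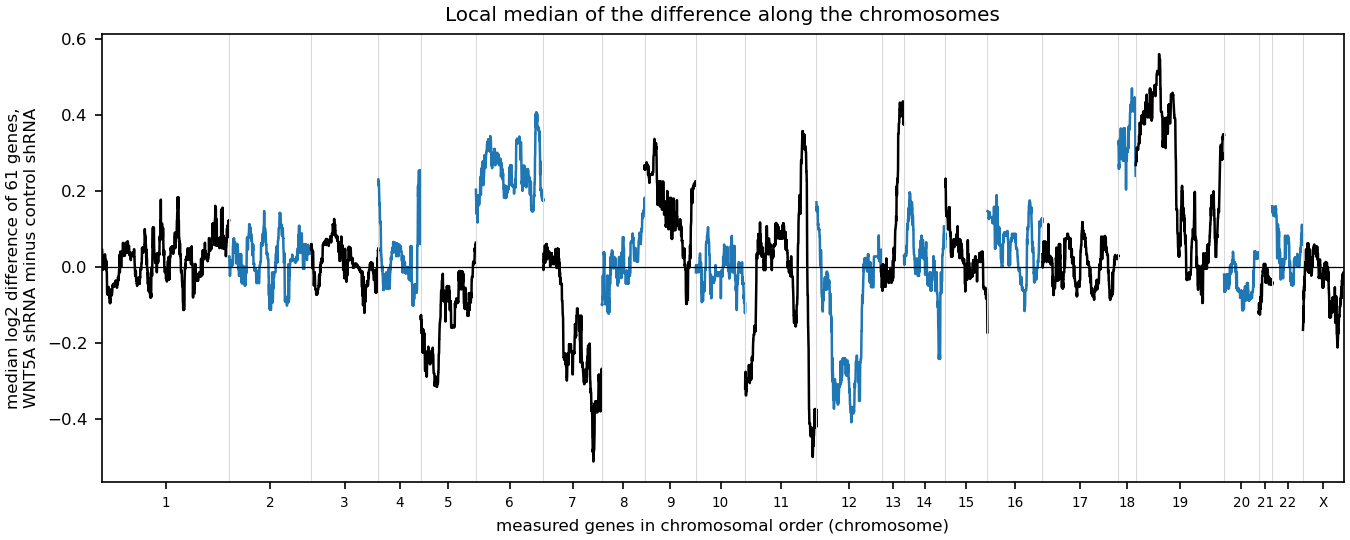
Median log2 difference of 61 neighbouring measured genes (y axis, WNT5A shRNA minus control shRNA) along each chromosome (x axis, genes in order, chromosomes in alternating colours); 1 array per group. Long stretches lie above 0 on chromosomes 6, 18 and 19 and below 0 on chromosomes 7 and 12.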

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

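Probes without a gene name took no part in the comparisons. Of these, 293 were at least 2-fold higher in the WNT5A shRNA array than in the control shRNA array and 300 were at least 2-fold lower, and 7022 were well above background on both arrays. What they detect was not analysed here.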

How the results depend on the processing

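With 1 array per group, leaving out a replicate, fitting the slide as a block and any paired fit could not be run, and both arrays shared 1 slide and scan. No paired analysis was possible because each group held 1 sample and no test was made. The WNT5A difference stayed between -1.55 and -1.46 over all alternatives. Of the 13 lists outside the limits, 9 kept their side under each of the 10 list alternatives, and 18 of 340 list percentiles crossed a limit. Of 1935 comparisons of named genes, 158 moved past the scanner error, 88 of them under normexp. None (0) of the 128 named genes at least 2-fold different reversed. A sign change of a smaller difference was not counted as a reversal. COL4A1 (0.37), for example, lay below its local median, so its sign changed with local medians removed. Normexp changed the background model, the offset and the intensity column together: 75 genes were higher and 244 lower past 2-fold (23.5% higher against 34.2%), and medians were -0.32 for TGF-beta response, 0.032 for hedgehog, -0.47 for Notch, 0.51 for interferon-stimulated, -0.13 for prostate epithelial and -0.22 for immune genes. Without the background filter more genes entered, 842 higher and 1340 lower, and the medians were 0.12 for NFAT and calcium response, -0.093 for matrix proteases, 0.13 for BMP, -0.39 for Notch, -0.50 for chemokines, -0.18 for hypoxia, -0.22 for metallothioneins, -0.045 for steroid receptors and 0.21 for endothelial markers, while prostate epithelial markers reversed to 0.026. With the mean of all probes, medians were -0.18 for matrix proteases, -0.14 for hypoxia and -0.14 for immediate early genes. With the local chromosomal median removed, an alternative chosen after the data were seen, medians were -0.74 for Notch, 0 for heat shock, -0.17 for cholesterol, -0.17 for immediate early (percentile 1.40), -0.028 for IGF-binding proteins and semaphorins, -0.034 for steroid receptors and -0.18 for fibroblast markers (percentile 1.69). The causes of these changes were not tested. At 1.5-fold 1136 genes were higher and 1545 lower, and at 3-fold 113 and 298. The SD of the differences was 0.647 in the dimmest 25% of genes and 0.334 in the brightest 25%.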

Other observations

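All gene groups of the first 2 paragraphs here were chosen after the data were seen, as were the tests of GC-rich chromosomes, of held-out genes for copy number, of H2B genes against H3 and H4 genes and against S phase, and of histone genes against probes of 1 gene. The tests of neighbours of the histone and CXC clusters were changed after a first result had been seen, from protein-coding to all measured neighbours. The histone genes and the NF-kB targets of the later paragraphs were also chosen after the data were seen. For the NF-kB targets, only the limit of the test was set before its result. The tests of a signal-dependent trend were set before their results were seen. Complement components and regulators were lower as a group, with 12 of 15 measured members below 0 and a median of -0.47 (percentile 0.01). The initiating proteases C1S (-1.65) and C1R (-1.07) and the central component C3 (-1.55) were at least 2-fold lower, and both probes of each gave the same direction. MHC class I and antigen processing genes had 16 of 17 members above 0 and a median of 0.37 (percentile 100), none past 2-fold; many of them lie on chromosome 6, whose median was 0.26. Other cytosolic RNA sensing genes had a median of 0.20 over 11 members (percentile 92.0), and replication-independent histone genes a median of -0.07 over 11 members (percentile 25.5).

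The imprinted cluster that holds MEG3 stood apart on chromosome 14. Of 21 measured genes 19 were at least 2-fold lower, with a median of -2.06, among them BEGAIN (-2.97), MEG9 (-2.41), MEG3 (-1.97, 6 probes between -2.61 and -1.47) and 16 of 17 small nucleolar RNA genes. DLK1, which is expressed from the paternal copy, stood at 0.07 on 1 probe with a scanner error of 0.233. RTL1 was well above background on neither array, and the parental copies were not compared here. SNORD114-19 was the only measured member past 2-fold higher (5.66-fold). The small nucleolar RNA copies are similar in sequence, so their probes are not independent readings.

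Stretches of neighbouring genes were shifted together, in 16 segments of at least 20 genes (9 higher, 7 lower); 1429 of 14530 genes had a local median past 0.3, against at most 0 in the shuffled orders. On chromosome 19, 279 genes from NDUFS7 to BRME1 had a median of 0.43 and 87.1% lay above 0, and on chromosome 11, 89 genes from PHLDB1 to B3GAT1-DT had a median of -0.42. A signal-dependent trend was argued against, since the SD of local medians was 0.155 before and after loess. The GC-rich chromosomes 17 and 22 lay within 0.0169 of the median of all genes, so they did not share the shift of chromosome 19 (0.24). GC content was not measured, so these 2 medians cannot exclude a shift of GC-rich genes. In segments defined on every other gene, 81.9% of 736 genes in between moved with their segment (603 genes), the brighter and the dimmer alike (medians 0.35 and 0.35). A difference in chromosome copy number between the 2 cell populations and a regional effect on expression would both give this, so they cannot be told apart without DNA data.

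Replication-dependent histone genes had a median of 0.32 over 63 genes, with 16 at least 2-fold higher and 2 lower. The 48 measured genes around and between those of the main cluster on chromosome 6 had a median of 0.299. The 53 histone genes of that cluster had a median of 0.297. That value mixes histone classes that differed, so the match does not settle what raised the group. A shift of the whole segment, by a gain or otherwise, was not excluded. It does not account for most of the 14 H2B genes, of which 10 were at least 2-fold higher (median 1.59, 3.02-fold, from H2BC6 at -1.17 and H2BC7 at -0.24 to H2BC12 at 2.04), since 22 H3 and H4 genes of the same cluster had a median of 0.107 (from -0.22 to 0.33); 12 H2A genes had a median of 0.50, with 3 past 2-fold, and 5 H1 genes 0.24, with H1-2 at 2.10. The S phase list had a median of 0.0741, with 18 of 24 members above 0, and showed no rise of the H2B size. How far this list moves with the share of cells in S phase was not measured, so a larger share was not excluded. The SD was 0.759 across histone genes, against 0.258 between measured probes of 1 gene, and H2B genes lay apart from H3 and H4 genes. A single transcript read by every histone probe would not give this, but the class values were known before that test was chosen. Cross-hybridisation among similar copies of 1 histone class and the share of polyadenylated histone transcripts were not tested, and an effect of the WNT5A shRNA stays open.

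The lower chemokine and cytokine signal was set against technical and regulatory explanations. Loss of the segment with the CXC chemokines was argued against, since 6 genes of that cluster had a median of -1.18 and 30 neighbours 0.0954. The list's median was -1.13 after loess, against -1.11 before. A signal-dependent trend of the size that loess fitted therefore does not account for the lower signal. The median stayed below each of the random lists, but these were matched on signal, so the percentile could not test a trend. A general drop of NF-kB targets was not seen in 28 other targets, with a median of 0.0173 (percentile 42.5), 14 of them below 0, from VCAM1 at -1.87 to BIRC3 at 1.36. An effect of the WNT5A shRNA and a difference between the 2 cultures both stay open and were not tested, since 1 array per group does not separate them; replicate cultures and a second WNT5A shRNA would be needed.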
